A study of Homo sapiens with 4 samples.

How the data were processed

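Chromatin immunoprecipitation with sequencing (ChIP-seq) of BAP18 was carried out in MCF7 cells, an estrogen receptor positive luminal breast cancer line. BAP18, encoded by BACC1 on chromosome 17, is a chromatin protein known as a subunit of complexes with the remodeler NURF and the histone methyltransferase MLL1. Per the labels, the cells received estrogen (E2) or its solvent ethanol (EtOH) for 1 h. The 4 samples were 1 BAP18 ChIP library per condition and 1 input library (chromatin without immunoprecipitation) for each. Groups were taken from the treatment labels of the ChIP samples and the titles of the inputs. A list of peaks was read for each ChIP sample, while the 2 input libraries were not analysed here other than through the background that enters each peak's values.

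The deposited fold enrichment of each peak is a ratio of immunoprecipitated to input signal made by the authors' peak caller, per the file headers. Each peak also has a deposited p-value and a false discovery rate (FDR), both on a linear scale per the file headers. The deposited pileup is a signal, the height of overlapping fragments, in whole numbers per the file headers. The deposited width in bp equals the end minus the start plus 1, with coordinates counted from 1. The genome build was hg38 and reads were handled with CASAVA 1.4, per the submitters' processing notes. The peak caller and the aligner are not given in the sources used here. The labels' protocols state an FDR limit of 0.01 and a fold enrichment over 2 for the sites the authors kept. The deposited lists run beyond those limits, to an FDR of 0.386 in EtOH and 0.807 in E2, and the highest p-values were 0.00952 and 0.00999. All deposited peaks were therefore the main set, and the peaks within the stated limits were an alternative chosen after seeing the data. The protocols also name a p limit for tag density, which was not used to choose a set of peaks because its exponent can be read in more than 1 way. Only the numbers of peaks under each reading, taken on the deposited p-value, are given. Peaks were called by the authors per library, so each list rests on 1 library.

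The total number of reads per library is not given in the sources used here, so the depth is unknown. The background of each peak was worked out as (pileup + 1) / fold enrichment − 1. The deposited p-value equalled the upper Poisson tail of the pileup at that background within 1% for 100% of the peaks in both lists. Its lowest value was 0.653 fragments in EtOH and 0.749 in E2. It is called the input background here. Low pileups limit precision, since 23.6% of the EtOH peaks and 29.4% of the E2 peaks rested on a pileup of 3 or 4 fragments.

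Peaks counted as shared when they overlapped by at least 1 bp. An own interval search was used and checked against bedtools 2.31.1, which gave the same 5314 E2 and 5173 EtOH peaks. As background, all peaks of a list were placed 100 times at random on their own chromosomes, and, as an alternative added later, shifted 100 times by 50 to 500 kb. The gene table used (hg38 assembly, 59675 genes) gives gene ends but neither strand nor exons. A start of transcription could therefore not be told from a 3′ end, and the promoter rule of the protocols was applied to both ends of each gene. A peak was at a gene boundary when its centre lay from 5000 bp outside to 100 bp inside either end of any gene. Other peaks lay inside a gene or outside genes. Counts per gene used the 19970 protein-coding genes on chromosomes 1 to 22 and X. The files give no summits, so peak centres were used.

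The 11 gene lists (251 genes) were the estrogen early targets, luminal identity, estrogen receptor (ER) coregulators, NURF and MLL1 complexes, CTCF and cohesin, steroid synthesis and metabolism, cell cycle, ribosomal proteins, basal and mesenchymal genes, genes of other tissues, and the 17q23 and 20q13 amplicons. The lists, the comparisons, the rule for named genes and most alternatives were fixed before the data were examined. All listed symbols were found in the gene table. For each list, the number of members with a peak was placed among 10000 random lists of protein-coding genes of the same size, matched on gene length in 10 classes. The percentile describes these libraries and is not a test of treatment.

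The named genes rule took, per list, up to 5 members with a boundary peak in both lists, up to 5 with one in EtOH only and up to 5 with one in E2 only, in order of fold enrichment in their own list, and up to 3 with none. It also took the gene nearest to each of the 10 peaks of lowest FDR among shared, EtOH-only and E2-only peaks. GREB1, TFF1, PGR, ESR1, FOXA1, GATA3, CTCF, BPTF, BACC1 and CYP19A1 were always described. Where several boundary peaks lay at a gene, the values are those of the peak with the highest fold enrichment. A gene counted in both lists can have its peaks at different places. A boundary peak can also lie nearer to a neighbouring gene than to the gene named, as with the peak counted for both RARA and CDC6.

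With 1 library per condition, no test between EtOH and E2 was possible and no p-value between conditions is given. Shares carry 95% Wilson intervals, which cover counting error only. Fold enrichment, FDR and pileup were the authors' values and were used to describe, rank or filter peaks of their own list. Where values or counts from both lists stand side by side, they were not scaled to each other here. A difference in them describes these libraries only. In the last part, the lowest background and the pileup of a few shared peaks were also compared between the lists. On simulated lists with a planted overlap of 26.94% the search returned 26.92%, and a planted boundary share of 37.59% returned 37.14%. Alternatives were higher limits on fold enrichment and FDR, equal numbers of peaks from each list, other overlap rules, other boundary zones and other distances to genes. Motif searches, classes by exon and intron, and random lists matched on CpG content were not run, because they need a genome sequence or transcript models not used here. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.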

Results

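BAP18 ChIP-seq was compared between MCF7 cells given estrogen for 1 h and cells given ethanol. The series asks where BAP18 sits in an estrogen receptor positive breast cancer line and how it relates to estrogen receptor alpha, CTCF and NURF. The data consisted of 1 peak list per condition, each called against its own input, with no replicate libraries. The EtOH list held 119852 peaks covering 40.7 Mb and the E2 list 52982 peaks covering 14.8 Mb, or 2.26 EtOH peaks for each E2 peak. The median peak was 272 bp wide with a 3.40-fold enrichment in EtOH, and 234 bp wide with a 3.20-fold enrichment in E2.

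The lists differed most in their highly enriched peaks. At the limits stated in the protocols (FDR of at most 0.01 and fold enrichment over 2), 27256 EtOH peaks and 1208 E2 peaks were left, which raised the ratio to 22.6. Peaks of at least 5-fold enrichment numbered 7089 in EtOH and 563 in E2. An FDR of at most 0.05 was met by 55.7% of the EtOH peaks and 7.004% of the E2 peaks. The gap was smaller at a common limit on the deposited p-value. With a fold enrichment over 2, the stricter reading of the protocols' p limit left 26245 EtOH and 4640 E2 peaks. The looser reading left 53671 and 14283. Compared with the stricter reading, the stated limits left more EtOH peaks but fewer E2 peaks. The same FDR was thus a stricter limit on p in E2 than in EtOH. No test of the difference was possible with 1 library per condition, and the depth of the libraries is unknown.

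On the main chromosomes, the peak of lowest FDR outside the ribosomal DNA lay at POMK, which encodes a protein O-mannose kinase, on chromosome 8 (43093076 to 43094342, centre 194 bp inside the gene). It had a 29.3-fold enrichment (FDR 6.15e-89) in EtOH, and the E2 peak at the same place had a 5.66-fold enrichment (FDR 3.96e-12). The other 9 of the 10 shared peaks of lowest FDR lay between 8206935 and 8438614 on chromosome 21, at or beside genes and pseudogenes of the 45S ribosomal RNA unit such as RNA45SN2, RNA5-8SN3, RNA18SN1, RNA28SN2 and RNA45SN3. The input background there was also high, from 7.93 to 37.4 fragments, against a median of 0.807 over the EtOH list. Among shared peaks with an input background under 5, a limit chosen after seeing the data, POMK was followed by HCG11, C3orf33, AP5B1 and SCAF8. The C3orf33 peak (chromosome 3, 155805442 to 155806530) had a 16.3-fold enrichment in EtOH and a 10.9-fold enrichment in E2.

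EtOH peaks of lowest FDR without an E2 peak lay at NCF1C (15.4-fold, chromosome 7, 75156524 to 75157502), PRSS21 (15.4-fold, chromosome 16, 2816987 to 2817552), LOC124902693, STAU1, ACTRT3, JMJD1C-AS1, NUDT3, LOC105379623, VPS4A and CYB561. The centres of the PRSS21, ACTRT3, NUDT3 and VPS4A peaks lay 32, 71, 261 and 206 bp from the nearer end of the gene, whether its start or its 3′ end. E2 peaks of lowest FDR without an EtOH peak had lower enrichment and lay elsewhere. The first, near LOC102724523 on chromosome 16, had a 1.71-fold enrichment over an input background of 143 fragments. The next was 149556 bp from MAP2K4 (chromosome 17, 12293222 to 12293547, 8.01-fold, FDR 1.45e-08). It was followed by peaks at the tRNA genes TRM-CAT3-2 (6.91-fold) and TRQ-TTG2-1 (6.37-fold) on chromosome 6. The remaining nearest genes were OR56B3P, TRG, TAF11L7, LOC124906350, MIR5091 and CDC27P10.

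Whether estrogen left BAP18 at the same places was addressed by overlap. An EtOH peak was touched by 5314 of the 52982 E2 peaks, 10.0% (95% Wilson interval 9.78 to 10.3), against 2.57% ± 0.0749 (SD over 100 random placements). In the other direction, 5173 EtOH peaks, 4.32% (4.20 to 4.43), touched an E2 peak, against 1.14% ± 0.0345. The share of EtOH peaks with an E2 peak rose with enrichment, although 3375 of the 5173 shared EtOH peaks were under 5-fold. Of the 320 EtOH peaks of at least 10-fold enrichment, 244 had an E2 peak, 76.2% (71.3 to 80.6), while the share was 22.96% (21.97 to 23.97) between 5-fold and 10-fold and 2.99% (2.90 to 3.09) below 5-fold. Of the 1208 E2 peaks within the stated limits, 699 touched an EtOH peak, 57.9% (55.1 to 60.6). The share of E2 peaks that were shared ranged from 4.37% with a reciprocal overlap of 50% to 87.4% among peaks with an FDR of at most 1e-05 in both lists.

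Shared peaks lay close to genes far more often than peaks found only in E2. Within 1000 bp of a protein-coding gene boundary lay 40.3% (39.0 to 41.7) of the shared E2 peaks, 11.02% (10.84 to 11.21) of the EtOH-only peaks and 2.57% (2.43 to 2.71) of the E2-only peaks. Random placement of the E2-only peaks gave 2.45% ± 0.0674. For all genes, 7.18% (6.95 to 7.42) of the E2-only peaks lay within 1000 bp of a boundary, above the 6.23% ± 0.129 at random. By the wider zone around all genes, 28.78% (28.52 to 29.04) of all EtOH peaks and 20.9% (20.5 to 21.2) of all E2 peaks lay at a boundary, against 17.4% ± 0.112 and 16.6% ± 0.164 at random. Shifts by 50 to 500 kb gave a higher background, at 22.7% ± 0.117 in EtOH and 18.5% ± 0.164 in E2. A further 49.3% and 48.4% lay inside genes, and 21.9% and 30.7% outside them. For all genes, the difference between the lists turned round at the stated limits, where 39.3% of the EtOH peaks and 47.9% of the E2 peaks lay at a boundary. For protein-coding genes, the intervals overlapped there, at 23.51% (23.01 to 24.02) in EtOH and 25% (22.64 to 27.52) in E2. Shared peaks made up 10.9% of the EtOH and 57.9% of the E2 peaks within these limits. Among the peaks not shared, the share at a boundary of any gene stayed higher in EtOH, at 36.8% against 21.8%. With the 1000 peaks of lowest FDR from each list, the boundary share for all genes was again higher in EtOH, at 63.1% against 49.9%.

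**Figure D1:**
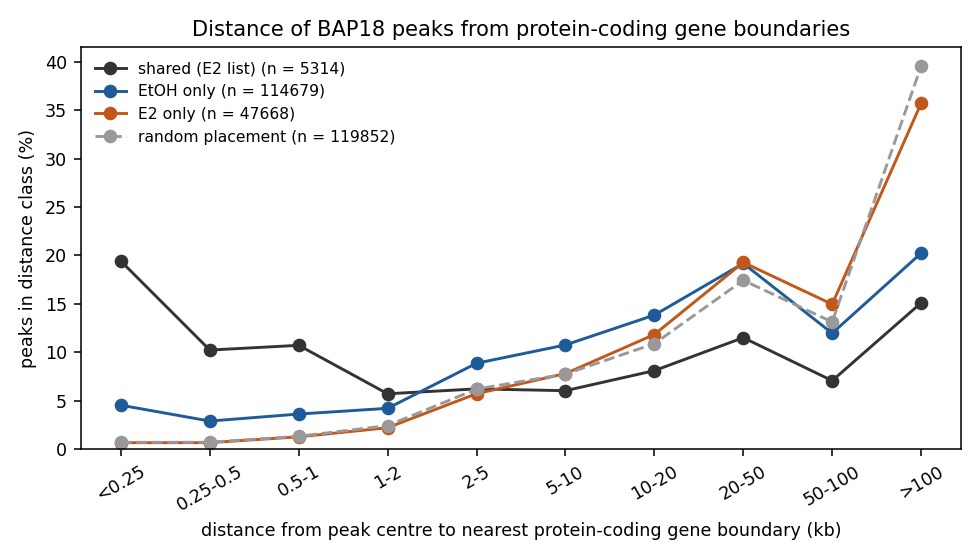
Share of peaks (%, y axis) by distance from the peak centre to the nearest protein-coding gene boundary (kb, x axis) for shared peaks of the E2 list, EtOH-only peaks, E2-only peaks and 1 random placement of the EtOH peaks. Within 250 bp lay 19.4% of the shared, 4.52% of the EtOH-only, 0.650% of the E2-only and 0.687% of the randomly placed peaks.

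The ratio of EtOH to E2 peaks differed between chromosomes and was highest on chromosomes 19, 22 and 17. Chromosome 19, with 24.8 protein-coding genes per Mb, had 87.3 EtOH and 18.6 E2 peaks per Mb, a ratio of 4.70. The ratio was 4.30 on chromosome 22 and 3.57 on chromosome 17. Chromosomes 5, 3 and 18, with 4.98, 5.38 and 3.36 genes per Mb, had ratios of 1.83, 1.83 and 1.87. The ratio did not follow gene density throughout, since chromosome 11 (9.63 genes per Mb) had 2.16 and chromosome 21 (5.12 genes per Mb) had 2.73. The densest megabase of the EtOH list was 1 to 2 Mb on chromosome 5, with 283 EtOH and 37 E2 peaks, and that of the E2 list was 27 to 28 Mb on chromosome 6, with 103 EtOH and 71 E2 peaks.

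**Figure D2:**
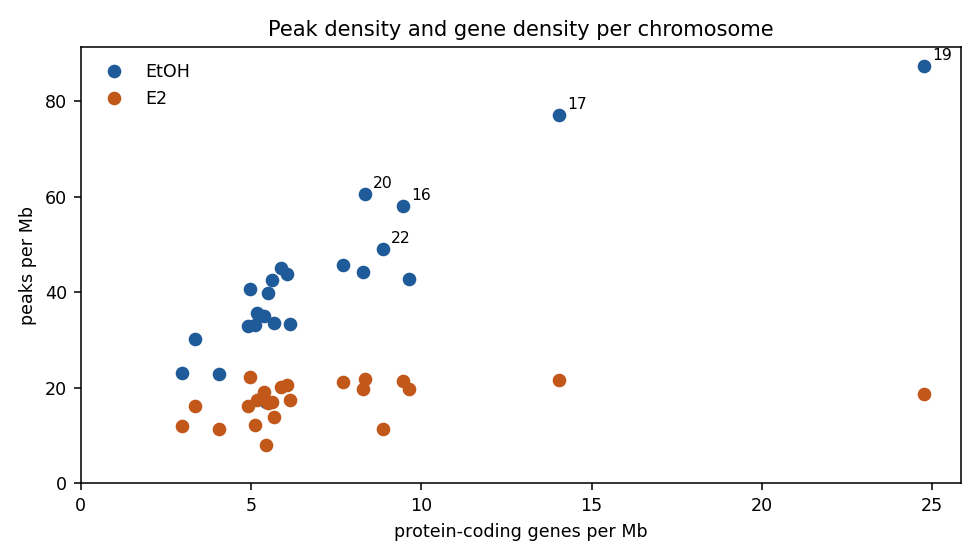
Peaks per Mb (y axis) against protein-coding genes per Mb (x axis), with 1 point per chromosome (1 to 22 and X) and list. EtOH peaks reach 87.3 per Mb on chromosome 19, where E2 peaks stand at 18.6 per Mb.

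The gene lists asked whether genes of estrogen response, luminal identity, NURF and CTCF carried BAP18 at their ends. Of all 19970 protein-coding genes, 12313 (61.7%) had a boundary peak in EtOH and 4578 (22.9%) in E2. Both lists had one at 3172 genes, where independent lists of these sizes would give 2823. EtOH alone had one at 9141 genes, E2 alone at 1406, and 6251 genes had none. With all peaks, ribosomal protein, cell cycle and ER coregulator genes stood highest in EtOH, and those of CTCF, cohesin, NURF and MLL1 in E2. Of the 3 in EtOH, only the ribosomal protein genes also stayed above the central 95% of random lists at 5-fold enrichment, at −log10 q of at least 5, at the stated limits and within 1000 bp of a gene end. Both E2 lists fell within the random range at 5-fold enrichment and at −log10 q of at least 5, and the NURF and MLL1 list also at the stated limits, where few E2 peaks were left. With equal numbers of peaks from each list both stood above it, at 6 of 14 and 6 of 15 genes (percentiles 99.67 and 99.4). No treatment effect on any list was tested, since each value rests on 1 library.

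Ribosomal protein genes had a boundary peak at 47 of 54 members in EtOH (percentile 99.995 of random lists) and at 18 of 54 in E2 (percentile 97.3). All 18 of these also had one in EtOH. RPL6 (8.82-fold in EtOH), RPS20 (8.47-fold) and RPL26 (7.75-fold) were among those with peaks in both, RPS14 (9.73-fold) and RPS3 (7.66-fold) among those in EtOH only. Cell cycle genes had one at 22 of 24 members in EtOH (percentile 99.86) and at 3 of 24 in E2 (percentile 10.6). Only 12 of 24 had one in EtOH at the stated limits (percentile 94.5), within the range of random lists, as were 4 of 24 at 5-fold enrichment (percentile 64.7). CCNE2, which encodes cyclin E2 (7.86-fold), the replication clamp gene PCNA (6.77-fold), the helicase gene MCM7 (6.16-fold) and the mitotic kinase gene AURKA (5.53-fold) had peaks in EtOH only. CDC25A, E2F2 and BUB1 had them in both, and CCNE1 and CDK1 in neither. CCNE1 and CDK1 each had an EtOH peak within 1000 bp of a gene end.

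ER coregulator genes had a boundary peak at 14 of 16 members in EtOH (percentile 99.2) and 5 of 16 in E2 (percentile 76.0). The histone acetyltransferase gene EP300 (chromosome 22, 41091581 to 41092992) had an 11.8-fold peak in EtOH and a 4.22-fold peak in E2, and the methyltransferase gene KMT2D had 6.91-fold and 3.65-fold peaks. CREBBP and PRMT1 also had peaks in both. MED1 (6.17-fold), KMT2C (6.16-fold) and NCOA1 (5.28-fold) had one in EtOH only, NCOA3 in E2 only, where the peak overlapped an EtOH peak centred outside the zone, and LCOR in neither. Within 1000 bp of a gene end, NCOA1 also had an E2 peak, and LCOR had EtOH peaks. At the stated limits, 12 of the 16 genes kept an EtOH peak (percentile 99.995) and 0 an E2 peak, while at −log10 q of at least 5 the EtOH percentile was 94.98 and within 1000 bp 90.6.

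NURF and MLL1 complex genes had a boundary peak at 10 of 15 members in EtOH (percentile 65.4) and 8 of 15 in E2 (percentile 99.2). BPTF, the largest NURF subunit, had a 7.75-fold peak in EtOH (chromosome 17, 67824686 to 67825783, FDR 1.31e-11) that overlapped a 4.06-fold peak in E2 (67825303 to 67825734, FDR 0.0367). RBBP5 (10.4-fold in EtOH), WDR5 (6.98-fold), KMT2A (6.24-fold), DPY30 (5.86-fold) and ASH2L, all of MLL1-type complexes, had peaks in both. HCFC1, RBBP4, HMGXB4 and MEN1 had one in EtOH only, although the RBBP4 peak overlapped an E2 peak centred outside the zone. KANSL1, SMARCA1 and SMARCA5 had no boundary peak, but each had 1 EtOH peak within 1000 bp of a gene end. RBBP7 and BACC1 had a boundary peak in E2 only, with FDRs of 0.268 and 0.160. At the stated limits 8 of the 15 genes had an EtOH boundary peak (percentile 95.9) and 0 an E2 one (percentile 38.8). At 5-fold enrichment 5 of 15 had an EtOH one (percentile 97.2) and 0 an E2 one (percentile 44.5). Both EtOH counts lay at the upper end of the random range, so the higher standing in E2 held for all peaks but not at these limits.

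CTCF and cohesin genes had a boundary peak at 9 of 14 members in EtOH (percentile 61.5) and 8 of 14 in E2 (percentile 99.7). NIPBL, the cohesin loader, had a 5.99-fold peak in EtOH (FDR 1.39e-15) and a 4.38-fold peak in E2 (FDR 0.000319). STAG2, PDS5B, SMC1A and PDS5A also had peaks in both, and WAPL (7.75-fold), MAU2, MAZ and ESCO2 in EtOH only. ESCO1 (5.04-fold, FDR 0.00460), the cohesin subunit gene RAD21 (4.90-fold, FDR 0.00474) and STAG1 (4.49-fold, FDR 0.00600) were counted in E2 only, but the RAD21 and STAG1 peaks overlapped EtOH peaks centred deeper in the gene. Within 1000 bp of either end of the gene, 14 of 14 members had an EtOH peak (percentile 99.87) and 7 of 14 an E2 peak (percentile 99.5). At the stated limits, 4 of 14 had an E2 boundary peak, against an upper end of 7.14% for the central 95% of random lists. The E2 count was within the random range at 5-fold enrichment (1 of 14, percentile 94.3) and at −log10 q of at least 5 (0 of 14, percentile 48.6).

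SMC3 and CTCF itself had no boundary peak by the zone rule. CTCF (chromosome 16, 67562526 to 67639177) nevertheless carried a 14.0-fold EtOH peak at 67561945 to 67563611 (FDR 2.34e-26), centred 252 bp inside the gene. An E2 peak overlapped it at 67563286 to 67563673 (4.50-fold, FDR 0.00912).

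**Figure D3:**
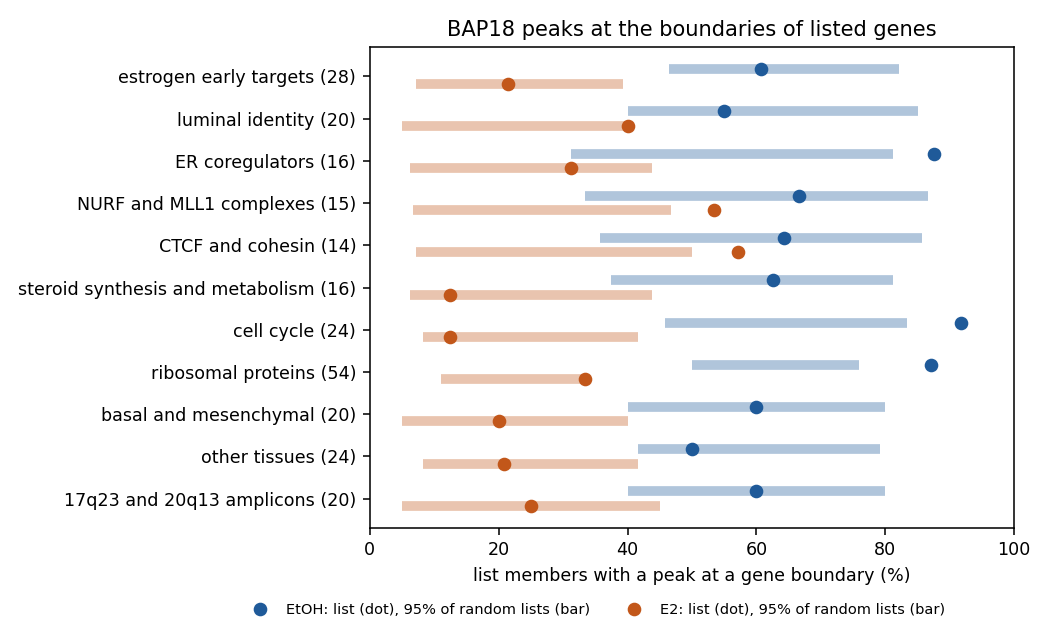
Share of list members with a peak at a gene boundary (%, x axis) for the 11 gene lists (y axis, number of genes in brackets), with dots for EtOH (blue) and E2 (orange) and bars for the central 95% of 10000 random lists. In EtOH the ER coregulators (14 of 16), cell cycle (22 of 24) and ribosomal proteins (47 of 54) lie beyond the bar, and in E2 the NURF and MLL1 complexes (8 of 15) and CTCF and cohesin (8 of 14) do.

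Estrogen early targets did not stand apart from random lists in either condition. A boundary peak was found at 17 of 28 members in EtOH (percentile 37.0) and 6 of 28 in E2 (percentile 44.7), and at the stated limits at 8 and 0. In EtOH only, SIAH2 (7.40-fold, FDR 7.76e-10), SGK3 (6.81-fold), MYC (6.75-fold, FDR 1.63e-08), EGR3 (6.14-fold) and STC2 (4.32-fold) had the most enriched peaks. CCND1, CXCL12 and FKBP4 had peaks in both, as did IGFBP4, whose peaks lay at opposite ends of the gene (7.12-fold at 40442771 to 40444151 on chromosome 17 in EtOH, 3.66-fold at 40460793 to 40461011 in E2). PGR, the progesterone receptor gene, had a 3.81-fold boundary peak in E2 only (FDR 0.0982), 3601 bp outside the gene. EtOH peaks lay 1562 bp (3.90-fold, FDR 0.0113) and 1329 bp (3.65-fold, FDR 0.0199) inside its ends, so the label rests on the zone. CA12 also had a boundary peak in E2 only (FDR 0.268), with an EtOH peak within 1000 bp of a gene end. ABCA3, AREG, FOS, GREB1 and TFF1 had no boundary peak. Within 1000 bp of a gene end, however, ABCA3 and AREG had peaks in both lists, and MYC also had an E2 peak.

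To take in distal sites, peaks were counted up to 50 kb from the gene, including those inside it or at its ends. Of all protein-coding genes, 98.0% had such an EtOH peak and 91.8% an E2 peak, so the counts were near their ceiling. All 28 estrogen early targets had one in EtOH and 27 in E2, against random means of 98.3% and 91.7%. At the stated limits 25 and 2 of 28 did (percentiles 74.7 and 37.6). Within 50 kb of GREB1 (chromosome 2, 11482888 to 11642788), a classical estrogen receptor target, lay 15 EtOH and 5 E2 peaks, of which 1 EtOH peak, inside the gene at 11582670 to 11583023 (4.26-fold, FDR 0.00442), met the stated limits. A shared peak lay at 11470557 to 11470802, 12209 bp from the gene. Around TFF1 lay 5 EtOH peaks and 1 E2 peak, which rested on a pileup of 3 fragments (FDR 0.807). At PGR there were 7 and 4. The stated limits left a peak within 50 kb in E2 at 7 of 14 CTCF and cohesin genes (percentile 99.985) and 6 of 15 NURF and MLL1 genes (percentile 99.88). The CTCF and cohesin count included the boundary peaks of NIPBL, RAD21, STAG1 and ESCO1. It also included the CTCF peak centred 953 bp inside the gene's end of lower coordinate, so it was not one of distal sites alone. BPTF had 16 EtOH and 3 E2 peaks, with a shared peak downstream at 68019928 to 68020495 (7.52-fold in EtOH, and 4.596-fold in E2 with an FDR of 0.00262). BACC1 had 10 and 4, the most enriched in E2 at 7048842 to 7049132 (4.99-fold, FDR 0.00361).

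**Figure D4:**
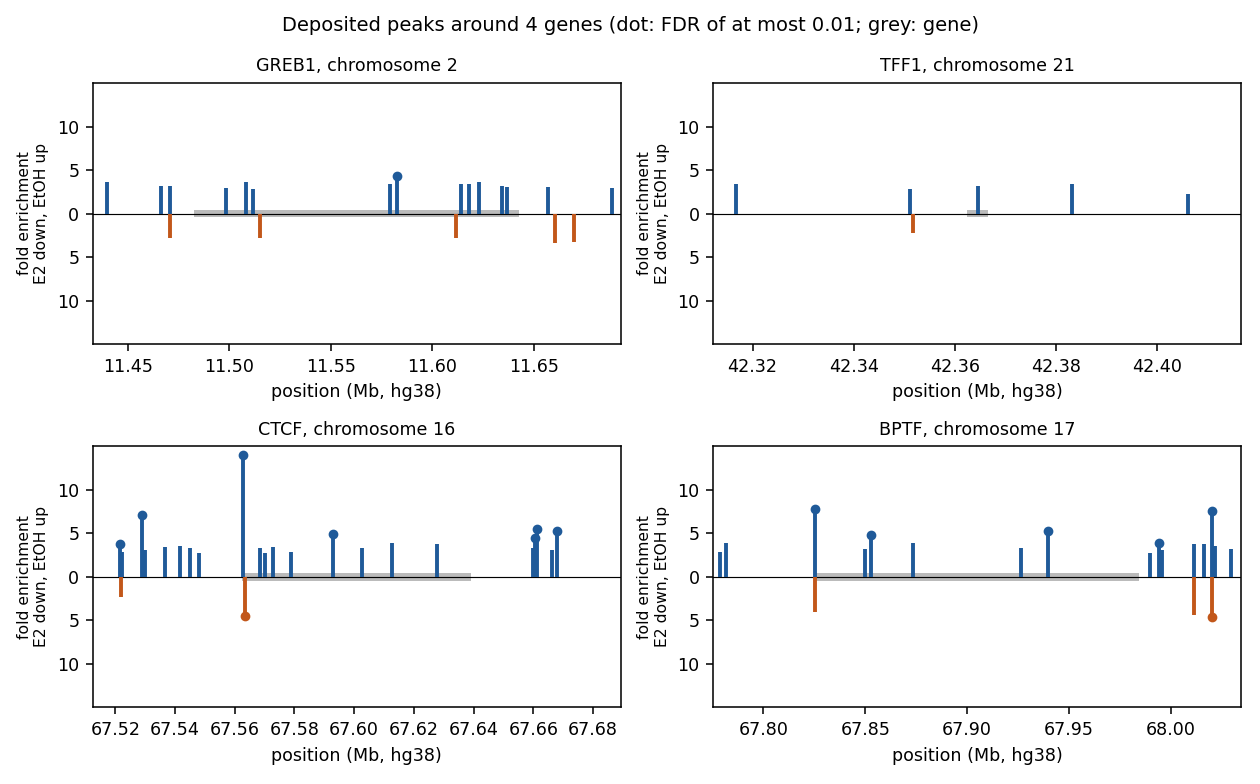
Deposited peaks (vertical lines at the peak centre, height the fold enrichment in the peak's own list, EtOH upward and E2 downward) around GREB1, TFF1, CTCF and BPTF within 50 kb of the gene (position in Mb, hg38), with dots at an FDR of at most 0.01. CTCF shows a 14.0-fold EtOH peak and a 4.50-fold E2 peak at the same end, while none of the 5 E2 peaks around GREB1 and the 1 around TFF1 carries a dot.

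Luminal identity genes had a boundary peak at 11 of 20 members in EtOH (percentile 25.1) and 8 of 20 in E2 (percentile 94.9). TBX3, a transcription factor of the luminal lineage, had the most enriched one in both lists (12.0-fold, FDR 2.59e-24 in EtOH, and 5.42-fold, FDR 2.78e-06 in E2). FOXA1 and CDH1 had peaks in both, TFAP2C, GATA3, CREB3L1, KRT8 and TFAP2A in EtOH only. The E2 boundary peak of FOXA1 rested on a pileup of 3 fragments (FDR 0.807), and that of CDH1 had an FDR of 0.494. GRHL2 (4.30-fold, FDR 0.0378), SPDEF (3.88-fold, FDR 0.101), MYB (FDR 0.288), ESR1 (FDR 0.494) and EPCAM (FDR 0.807) had one in E2 only. The ESR1 and EPCAM peaks each rested on a pileup of 4 fragments. SPDEF and EPCAM each also had 1 EtOH peak within 1000 bp of a gene end, deeper in the gene than the zone reaches, and TFAP2C had 1 such E2 peak. KRT18, KRT19 and PBX1 had no boundary peak, although KRT18 and PBX1 each had 2 EtOH peaks within 1000 bp of a gene end. At the stated limits 2 of 20 genes had an EtOH peak (percentile 1.395) and 1 an E2 peak. Within 50 kb, ESR1 had 15 EtOH and 9 E2 peaks, the most enriched an EtOH peak inside the gene on chromosome 6 (151764350 to 151764602, 6.81-fold). FOXA1 had 11 and 2, including a shared peak inside the gene (EtOH 37594360 to 37594845 on chromosome 14, 4.04-fold, and 4.79-fold with an FDR of 0.00921 in E2), and GATA3 had 7 and 5.

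Steroid synthesis and metabolism genes had a boundary peak at 10 of 16 members in EtOH (percentile 54.1) and 2 of 16 in E2 (percentile 16.7). SULT1A1, a phenol sulfotransferase gene, had one in both (5.58-fold in EtOH, 6.27-fold in E2), as did CYP1B1. COMT (5.81-fold), HSD17B8 (5.03-fold) and CYP19A1, which encodes aromatase (3.97-fold, FDR 0.0114), had one in EtOH only. Within 50 kb CYP19A1 had 11 EtOH and 9 E2 peaks.

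The comparison lists gave 12 of 20 basal and mesenchymal genes in EtOH (percentile 46.9) and 4 in E2 (percentile 39.7), with CDH2, MYLK, SNAI2 and KRT14 in both. Amplicon genes gave 12 of 20 and 5 of 20 (percentiles 49.9 and 58.8), led by the clathrin gene CLTC (14.3-fold, FDR 2.67e-31 in EtOH). Genes of other tissues gave 12 of 24 and 5 of 24 (percentiles 12.98 and 43.95). Within 1000 bp of a gene end they gave 5 of 24 in EtOH (percentile 0.0050) and 1 of 24 in E2 (percentile 4.71). SFTPC, a lung surfactant gene, had the most enriched boundary peak among them (7.91-fold in EtOH). It lay at 22165154 to 22165644 on chromosome 8, outside the gene (22157383 to 22164479), and may belong to a neighbouring gene.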

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

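The settings of an FDR of at most 0.01 with a fold enrichment over 2, an input background under 5, the 1000 peaks of lowest FDR and the shift by 50 to 500 kb were chosen after seeing the data, and the other settings given here before the data were examined. No paired analysis was possible because each condition has 1 library and no result comes from a test between replicates. Motif searches, exon and intron classes and random lists matched on CpG content were not run. The EtOH list was longer than the E2 list at each limit on fold enrichment, FDR or input background, but shares moved with the strictness of the list. The cause was not tested, other than that stricter limits leave fewer peaks by construction.

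Peaks in EtOH and E2 numbered 7089 and 563 (ratio 12.6) at 5-fold enrichment, 4613 and 206 (22.4) at −log10 q of at least 5, and 27256 and 1208 (22.6) at the stated limits. The counts given above at common p-value limits lay closer together than these. The share of E2 peaks and of EtOH peaks that were shared was 42.6% and 3.39% at 5-fold, 87.4% and 3.69% at −log10 q of 5, 8.07% and 7.70% with equal numbers, 53.1% and 2.27% at the stated limits, 9.71% and 4.19% at an input background under 5, 32.6% and 30.4% in the top 1000, 4.37% and 1.93% with reciprocal overlap, and 6.91% and 3.06% with centres within 200 bp. It was 55.4% and 25.4% for 5-fold peaks against the whole other list, and merging within 1000 bp gave 4.70% of EtOH peaks.

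The boundary share in EtOH and E2 was 52.0% and 44.4% at 5-fold, 59.9% and 65.5% at −log10 q of 5, 39.5% and 21.8% with equal numbers, 39.3% and 47.9% at the stated limits, 63.1% and 49.9% in the top 1000, 18.5% and 11.6% within 1000 bp, and 14.9% and 8.69% for protein-coding genes. For all genes, EtOH minus E2 reversed to -5.59 and -8.67 percentage points at −log10 q of 5 and the stated limits. It was 17.7, 13.2, 6.87 and 6.21 points with equal numbers, in the top 1000, within 1000 bp and for protein-coding genes with all peaks. At the stated limits, protein-coding genes gave 23.51% in EtOH and 25% in E2, with overlapping Wilson intervals.

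Estrogen early targets with a boundary peak in EtOH were 17.9% at 5-fold and at −log10 q of 5, and 28.6% with equal numbers and at the stated limits. In E2 they were 0% at all 3 limits, and 0 lists stood above the central 95% of random lists in E2 at 5-fold and −log10 q of 5. Within 50 kb they were 57.1% and 50% in EtOH at 5-fold and −log10 q of 5. In E2 they were 0% at both, 78.6% with equal numbers, 7.14% at the stated limits, 75% within 10 kb and 100% within 100 kb. Lists above that range within 50 kb numbered 2, 4, 1 and 1 in EtOH at 5-fold, −log10 q of 5, equal numbers and the stated limits, 1 within 10 kb, and 2 in E2 at the stated limits. Of the values for the other lists and the always described genes, 268 stayed within their interval, or for counts within a fixed ratio, and 172 moved. By the same rules, 55 of the main values stayed, 69 moved and 2 reversed.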

Other observations

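All values and tests in this part were chosen after the main results were seen. The tRNA genes, transcribed by RNA polymerase III, stood out in both lists. Of 443 tRNA genes, 237 had an EtOH peak centre within 500 bp, 53.5% (95% Wilson interval 48.8 to 58.1), and 206 an E2 peak, 46.5% (41.9 to 51.2), against 4.52% and 2.01% when the genes were put at random positions. At the stated limits the shares were 44.9% (40.4 to 49.6) and 23.7% (19.98 to 27.88), against 1.00% and 0.0429%. Peaks at tRNA genes were 84 of the 1208 E2 peaks within the stated limits, 6.95% (5.65 to 8.53), and 173 of the 27256 EtOH peaks, 0.635% (0.547 to 0.736). Many tRNA genes lie in clusters, so neighbouring genes were not independent. Their E2 peaks had a median input background of 1.83 fragments, against 1.21 over the E2 peaks within the stated limits and 14.6 at rRNA genes. Small nuclear RNA genes had an EtOH peak at 23.4% and an E2 peak at 9.09% of 154 genes, against 6.36% and 2.08% at random positions, and snoRNA genes at 5.52% and 1.42% of 1196, against 4.54% and 1.92%. The shares were 14.3% and 3.56% of 1911 miRNA genes, against 4.72% and 1.95%. They were 24.5% and 20.4% of 49 rRNA genes, against 8.37% and 3.14%.

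Gene families also differed. Histone genes had a boundary peak at 80 of 92 members in EtOH and 46 of 92 in E2, both at percentile 100 of random lists, but at 4 of 92 in E2 at the stated limits (percentile 95.6). HOX genes, the body-axis transcription factors, had one at 33 of 40 and 18 of 40 (percentiles 99.8 and 99.96), but 0 of 40 in E2 at the stated limits. Olfactory receptor genes had one at 91 of 392 in EtOH (percentile 0) and 69 of 392 in E2 (percentile 3.21), and keratin-associated protein genes at 22 of 94 and 13 of 94 (percentiles 0 and 6.48). Members of these families lie in clusters, which random lists of scattered genes do not copy. The zinc finger ZNF genes did not stand apart on all peaks, at 320 of 517 in EtOH and 114 of 517 in E2 (percentiles 15.1 and 21.5). At the stated limits they stood low in EtOH, at 120 of 517 (percentile 0), but not in E2 (7 of 517, percentile 22.7).

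The E2 list was far shorter than the EtOH list. Its lowest input background was 1.15 times that of EtOH, but how the input was scaled to each ChIP library is not known. The pileup at 8 shared peaks with fold enrichment under 2 in both lists had a median E2 to EtOH ratio of 1.09 (range 0.838 to 1.17). These peaks lay only on chromosome 1 and on contigs outside the main chromosomes, with E2 pileups of up to 375. Neither value showed fewer fragments in the E2 library, but neither measures depth over the genome, so fewer fragments stay open. Weaker enrichment in the E2 library stays open too. The share of EtOH peaks with an E2 peak was 25.5 times as high at 10-fold enrichment or more as under 5-fold, but strong peaks recur more than weak ones under any of these explanations, so the value decides nothing. A change of BAP18 binding after estrogen also stays open, with 74.6% of the EtOH peaks of at least 5-fold enrichment lacking an E2 peak, and cannot be told apart from weaker enrichment with 1 library per condition.

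Peaks found only in E2 differed little from peaks shifted by 50 to 500 kb, and not in 1 direction. Within 1000 bp of a boundary lay 2.57% against 2.68% ± 0.0770 (SD over 100 shifts) for protein-coding genes and 7.18% against 6.80% ± 0.126 for all genes, and in the wider zone 6.21% against 6.72% ± 0.103 and 17.79% against 17.99% ± 0.195. For the protein-coding share within 1000 bp the ratio was 0.957 in the form of the test run first and 1.11 (0.994 to 1.247) with shifts to places with no EtOH peak, whereas that for EtOH-only peaks was 2.77. Chance pileups may make up most of these E2-only peaks, and the highest FDR the authors gave in the E2 list was 80.7%. Nearness to genes cannot tell chance pileups from real sites away from genes. Of the E2-only peaks within the stated limits (509 of 47668, 1.07%), a similar share of 3.34% (2.10 to 5.28) lay within 1000 bp of a protein-coding gene boundary. Recruitment of BAP18 by estrogen to sites away from genes stays open, since no other E2 library was there to show whether E2-only peaks recur.

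The EtOH surplus grew with gene density, from 1.24 EtOH peaks per E2 peak in megabases with no protein-coding gene to 3.44 in those with 9 or more. Peaks at gene boundaries alone do not account for it, since the ratio outside genes and boundaries also rose, from 1.22 (95% counting interval 1.16 to 1.28) to 2.47 (2.37 to 2.58). A trend over whole regions in one of the libraries, such as base composition, could give such a rise and stays open, since no genome sequence was used here to measure it. An effect of estrogen on gene-dense regions was not tested apart from this, with 1 library per condition.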
